A study of Drosophila melanogaster with 4 samples.

How the data were processed

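ATAC-seq, in which the Tn5 transposase cuts accessible DNA and inserts sequencing adapters, was performed on nuclei of Drosophila S2 cells, an embryonic cell line with hemocyte-like properties. The labels describe 4 libraries. Of these, 2 were controls treated against LacZ, a bacterial gene with no counterpart in the fly, and 2 came from cells depleted of the linker histone H1. The numbers 1 and 2 in the titles name the libraries of each group.

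Per the submitters' processing notes, the genome build was dm3 and the tools were Bowtie2, a read aligner, and Genrich 0.5, a peak caller. Aligner version, options, filters, the treatment of reads with several equally good placements, and any pooling of libraries before peak calling are not given in the sources used here. The authors deposited 2 peak lists. Each has 10 columns in the order of the narrowPeak format and no header. The labels of all 4 libraries name both lists, and no label ties a list to the control or to the H1-depleted cells. The lists were therefore not assigned to a group. The longer is called list A and the shorter list B, and no difference between them is a difference between control and knockdown in the text. With 1 list of each kind there is no replicate. Whether the lists share libraries is unknown, and no test across samples could be made.

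The deposited signal column is read as the area under the caller's significance curve over a peak, called peak strength here, from its place in the format. Its lowest value was 20.0 in list A and 20.1 in list B. The deposited score equalled 1000 times the area per base, capped at 1000, in all 5145 peaks of list A and all 4027 of list B. The deposited summit p-values and q-values are given as −log10, by the caller. The lowest −log10 q was 1.54 in both lists. Among the other deposited columns, the start, end and summit offset are whole numbers. Within each list neighbouring peaks were at least 101 bp apart. Strength and q depend on the depth and background of the libraries behind a list, so they were used only to describe and rank peaks within 1 list. Read depth per library is unknown, because the lists carry no read counts.

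All else was computed from the lists, with bedtools 2.31.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks of the lists were called shared when they overlapped by at least 1 bp. Coordinates are 1-based in dm3. Chromosomes were grouped into the major arms (2L, 2R, 3L, 3R and X), chromosome 4, heterochromatic scaffolds (names ending in Het) and unplaced scaffolds (U and Uextra). In dm3, Uextra is a string of small scaffolds of lower quality that could not be placed. Arm peaks were called proximal when their midpoint lay within 2 Mb of the end nearest the centromere. That end was coordinate 0 on 2R and 3R and the last peak end of either list on 2L, 3L and X. Shares carry exact (Clopper-Pearson) 95% intervals, and medians carry the binomial interval of the order statistics. Odds ratios carry 95% intervals by the Robins-Breslow-Greenland formula, and those adjusted for strength were pooled over 10 equal parts of list A by the Mantel-Haenszel method. All intervals treat peaks as independent and cover counting error only. They say nothing about the spread between cultures. Chance overlap was taken from 100 shuffles of list B within its chromosomes. Windows of 100 kb in which list-only peaks of 1 list outnumbered those of the other by 5 or more were counted, and set beside 100 permutations of the list labels within chromosomes. The list-only peaks of Uextra were set beside 10000 random draws in proportion to the list A peaks of each of its 29 bins of 1 Mb.

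The overlap, the odds ratios, the width ratios and the window counts were tested on simulated data. Lists were made from list A with known losses. An odds ratio of 6 was recovered as 6.00 (95% interval 4.99 to 7.22) over 5145 peaks. A simulated loss of 40.5% of arm peaks was recovered as 40.5%, a log2 width ratio of -0.32 as -0.32, and 1 window with a gained cluster as 1 window. With losses set by strength alone, an odds ratio of 1 was recovered as 0.908 (0.781 to 1.06). These are checks of the code. The losses followed the same strength values that define the parts, so they do not stand for a list called on a signal of its own.

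Except where the text says otherwise, the peaks named were fixed by a rule before the data were examined, as were the chromosome classes, the proximal distance and most alternatives tried. The rule took the 10 strongest list-only peaks of each list on the arms and chromosome 4, the 5 strongest on scaffolds, the 5 shared peaks with the best summed rank, and the 3 windows with the largest excess in each direction. Shared peaks entered the rule only as one-to-one pairs. Alternatives were a reciprocal overlap of 50%, the stronger 50% of each list, list A trimmed to the length of list B, arms and chromosome 4 only, a proximal distance of 1 Mb, windows of 50 kb and merging within 100 bp. Merging within 500 bp and leaving out regions were added after the data were seen. The gene table used here is of Release 6, another build, so no gene, promoter or gene list was joined to the peaks. It served only to count neighbouring histone genes by name.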

Results

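Chromatin accessibility was profiled by ATAC-seq in Drosophila S2 cells, with 2 control libraries treated against LacZ and 2 libraries depleted of histone H1, the linker histone that binds nucleosomes and the DNA between them. The series concerns the role of H1 at heterochromatin, the compact and repeat-rich part of the genome around the centromeres. The data are 2 lists of accessible regions in dm3, which the labels tie to all 4 libraries and to neither group. List A held 5145 peaks that covered 2.07 Mb, with a median width of 261 bp (interquartile range 167 to 447). List B held 4027 peaks that covered 1.69 Mb, with a median width of 265 bp (174 to 451). The comparisons below are between these lists and not between conditions. There are no replicates, so each interval covers counting error only.

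The lists marked largely the same places, and the strongest regions of each were found in both. In list A, 3442 peaks (66.9%, 95% interval 65.6 to 68.2) overlapped a list B peak. In list B, 3535 peaks (87.8%, 86.7 to 88.8) overlapped a list A peak. Shuffled positions gave on average 1.97% of list A and 2.32% of list B, and at most 2.41% and 2.83% over 100 shuffles. Shared bases came to 1.56 Mb, 75.6% of list A and 92.5% of list B, a Jaccard index of 0.71. All of the 100 strongest peaks of each list overlapped the other list, and 90 of the 100 strongest in list A overlapped one of the 100 strongest in list B.

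The strongest shared regions were kilobases long, and 2 of the 5 pairs lay on Het scaffolds. Strength is an area summed over the width of a peak, so this ranking favours long regions. The top pair by rank was on 3RHet, from 787656 to 791820 in list A and from 787656 to 791821 in list B. It was followed by a region of 3LHet from 1279172 to 1285649, which was 6478 bp wide in list A and 6454 bp wide in list B. A region of 3L from 20469944 to 20475540 was 5597 bp wide in list A and 5592 bp in list B. The other 2 pairs lay close together on 2L, from 20176890 to 20183702 and from 20190728 to 20197534 in list A. These peaks, another between them starting at 20183811, and a peak on X from 1522171 to 1528981 had the same summit −log10 p of 15.1 in list A, and widths of 6807 to 6813 bp. The last 2 were picked after this match was seen. The corresponding 4 peaks of list B also shared a −log10 p, of 14.1. Whether the 4 regions are separate signals was not tested. The strongest single peak of either list, which the one-to-one rule left out and which was picked after its value was seen, was on U. It ran from 5288465 to 5303488 in list A and from 5288470 to 5302047 in list B.

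The lists differed in how their peaks were spread between the chromosome arms and the repeat-rich scaffolds, the comparison closest to the heterochromatin in the title of the series. List A held more peaks on every major arm, and list B held more on the unplaced scaffolds. The major arms carried 3675 peaks in list A and 2261 in list B, 71.4% (70.2 to 72.7) and 56.1% (54.6 to 57.7) of the lists. The ratio of list B to list A was 0.65 on 2L, 0.59 on 2R, 0.59 on 3L, 0.62 on 3R and 0.63 on X. The unplaced scaffolds carried 1242 peaks in list A (24.1%, 23.0 to 25.3) and 1556 in list B (38.6%, 37.1 to 40.2). The odds of lying on the arms were 1.95 times as high in list A as in list B (1.79 to 2.13), or 1.54 times (1.34 to 1.77) without Uextra, and the odds of lying on unplaced scaffolds were 0.505 times as high (0.462 to 0.553).

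Numbers on the heterochromatic scaffolds and on chromosome 4 lay close together. The Het scaffolds held 214 peaks in list A and 199 in list B, an odds ratio of 0.835 (0.685 to 1.02) whose interval includes 1. That depended on Uextra, without which the Het scaffolds took a smaller share of list A than of list B (odds ratio 0.687, 0.563 to 0.838). Without the end of Uextra and a block of 2L, both described further on, it was 0.784 (0.644 to 0.956). Chromosome 4, the small and largely heterochromatic autosome, held 14 and 11 peaks, too few to show a difference (odds ratio 0.996, 0.452 to 2.20). The larger Het scaffolds followed the same pattern, with 78 and 75 peaks on 2RHet, 72 and 64 on 3RHet, and 43 and 40 on 3LHet. Within the unplaced scaffolds the numbers on U were 250 and 244, while Uextra held 992 peaks in list A and 1312 in list B. In bases, the unplaced scaffolds took 21.7% of list A and 30.0% of list B, and the arms took 71.7% and 62.2%.

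**Figure D1:**
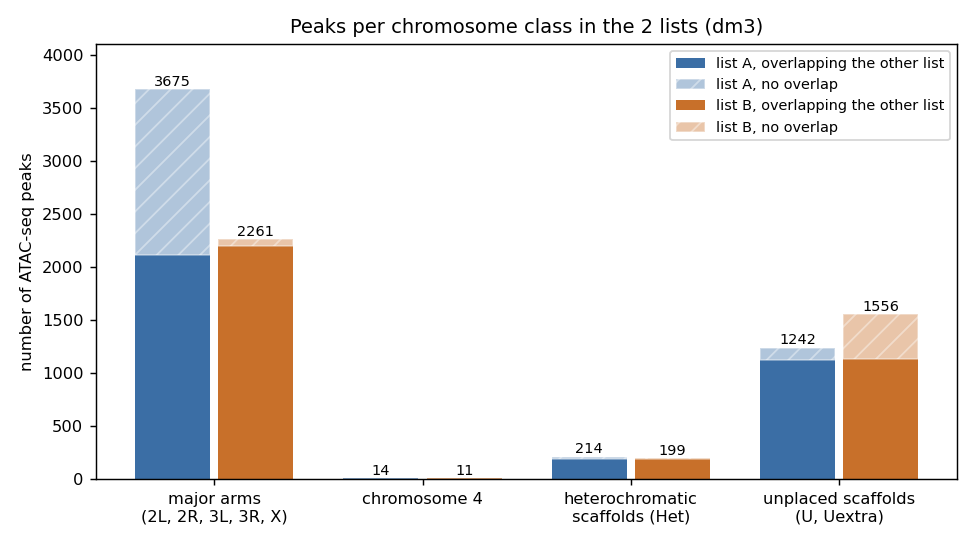
Number of ATAC-seq peaks (vertical axis) per chromosome class in list A (blue) and list B (orange), with solid bars for peaks that overlap the other list and hatched bars for those that do not. On the major arms list A rises to 3675 peaks against 2261, while on the unplaced scaffolds list B holds 1556 against 1242.

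Peaks present in 1 list alone were divided between the classes in opposite ways. Of the 1703 list A peaks without a partner, 1560 were on the major arms, which is 42.4% of the list A arm peaks (40.8 to 44.1). Only 10.7% of its Het peaks (6.94 to 15.7) and 9.42% of its unplaced peaks (7.85 to 11.2) had no partner. Of the 492 list B peaks without a partner, 411 were on Uextra and 59 on the arms. On the arms, 97.4% of list B peaks (96.6 to 98.0) had a list A partner, as did 96.5% of its Het peaks (92.9 to 98.6) and 11 of 11 on chromosome 4 (71.5 to 100%). On the unplaced scaffolds the share was 72.6% (70.3 to 74.8).

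Within each list, peaks without a partner were weaker than shared ones. The median list-only peak stood at percentile 21.0 of list A by strength (19.7 to 22.3) and at percentile 29.7 of list B (25.6 to 34.1), against 66.0 and 53.3 for shared peaks. In list B this value rested on the unplaced scaffolds (34.1), since list-only peaks stood at percentile 9.03 on the arms and 5.92 on the Het scaffolds. Without Uextra it was 9.48. The share of list A arm peaks without a partner was followed over 10 equal parts of the list, from weakest to strongest. It went from 93.6% in part 1 to 46.9% in part 5 and 2.54% in part 8. In part 9 it was 0 of 346 arm peaks, which allows a share of up to 0.867% as 3 counts of the total and up to 1.06% by the exact interval. Scaffold peaks in parts 1, 5 and 8 lacked a partner in 51.6%, 0.680% and 0.833% of cases. Within parts of equal strength, the odds of lacking a partner were 16.2 times as high on the arms as on the Het and unplaced scaffolds (12.3 to 21.3), against 6.93 (5.76 to 8.35) without regard to strength.

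**Figure D2:**
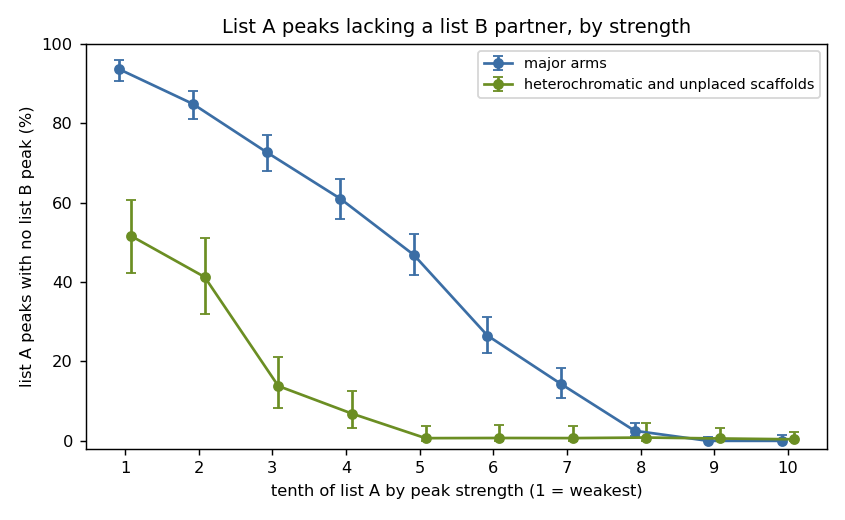
Share of list A peaks with no overlapping list B peak (percent, vertical axis) in each of 10 equal parts of list A by peak strength, from weakest to strongest, for the major arms (blue) and the heterochromatic and unplaced scaffolds (green). Bars are exact 95% binomial intervals. The arm share lies above the scaffold share in the weakest parts (93.6% against 51.6% in part 1) and both are near 0 in the strongest.

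The strongest list A arm peaks without a partner were on 3R from 5756824 to 5757563 (740 bp, −log10 q of 3.79), on 3L from 2823447 to 2824136 (690 bp, 3.3) and on 3R from 1089721 to 1090058 (338 bp, 3.87). The nearest list B peaks were 2302 bp, 2091 bp and 181747 bp away. The 10 strongest spread over 2L, 3L, 3R and X, and their −log10 q ran from 2.85 to 3.87. On the scaffolds, 1 list A peak without a partner stood apart. It lay on Uextra from 11425844 to 11426204, had a −log10 p of 24.2, and was the only one of the 1703 in the strongest 10% of list A. Of the 10 strongest list B arm peaks without a partner, 9 lay on 2L between 21417169 and 21536985 and the other on 3R from 19166368 to 19166652. The strongest list B scaffold peaks without a partner were on Uextra from 7470314 to 7470630 (−log10 q of 5.09) and from 28073592 to 28073965 (5.57).

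Arm peaks close to the centromere made up a larger share of list B than of list A over all arms together. Within 2 Mb of the proximal ends lay 338 of 3675 arm peaks in list A (9.20%, 8.28 to 10.2) and 280 of 2261 in list B (12.4%, 11.1 to 13.8), an odds ratio of 0.717 (0.606 to 0.848). Without a block of recurring list B peaks on 2L, described further on, the shares were 9.15% and 11.4% (odds ratio 0.782, 0.659 to 0.929). The odds ratio was 0.732 (0.583 to 0.919) within 1 Mb of the ends and 0.771 in the stronger 50% of each list, where the interval of 0.597 to 0.995 came close to 1. On 3R the share was 6.85% in list A and 6.69% in list B, while on 2L, 2R, 3L and X it was higher in list B. Proximal list A peaks had a list B partner in 71.3% of cases (66.2 to 76.1) and the other arm peaks in 56.2% (54.5 to 57.9). Arms differed in this. The proximal and distal shares were 83.1% and 53.2% on 3L, 81.3% and 54.9% on X, and 76.4% and 54.3% on 2R, but 59.3% and 59.4% on 3R and 55.6% and 58.5% on 2L. Over all arms together, distal list A peaks lacked a partner more often than proximal ones. The odds were 4.25 times as high within parts of equal strength (3.02 to 5.98), against 1.94 (1.52 to 2.48) without regard to strength.

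Shared regions were narrower in list B on the arms and of nearly equal width on the scaffolds. Over all 3274 one-to-one pairs the median log2 ratio of list B to list A width was -0.09 (-0.10 to -0.08), but it was -0.046 in the stronger 50% of each list and -0.15 without Uextra. Of the 1984 one-to-one pairs on the major arms, 1710 (86.2%) were wider in list A, with medians of 355 bp and 285 bp. The median log2 ratio was -0.20 (-0.21 to -0.18), a width 12.7% smaller. On the unplaced scaffolds it was -0.01 (-0.02 to -0.01) over 1103 pairs, and on the Het scaffolds -0.02 (-0.03 to -0.01) over 176 pairs. Summits of paired peaks lay a median of 6 bp apart on the arms and 1 bp apart on both kinds of scaffold.

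The windows with the most list-only peaks lay on the arms for list A and on Uextra for list B. List A peaks were in excess by 5 or more in 73 windows of 100 kb, of which 72 were on the major arms. The number was 24 with peaks within 500 bp merged, 13 in the stronger 50% of each list and 47 in windows of 50 kb. The largest excesses were on 3R from 25.6 to 25.7 Mb (14 list A peaks without a partner against 1), and on 2R from 3.5 to 3.6 Mb and 2L from 21.6 to 21.7 Mb (11 against 0 in each). List B peaks were in excess in 10 windows, 8 of them on Uextra and 2 on 2L. That number was 6 in the stronger 50% of each list, 2 without Uextra, and 1 without the end of Uextra and the 2L block described below. The largest 3 were on Uextra, from 28.8 to 28.9 Mb (40 against 0), 28.9 to 29.0 Mb (37 against 0) and 28.7 to 28.8 Mb (35 against 0). Permuted labels gave a mean of 69.97 windows for list A and 9.35 for list B. Because most list-only peaks of an arm or of Uextra belonged to 1 list, and the permutations kept their positions, these counts could change little and do not show whether list-only peaks cluster.

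The 2 places described next were picked after their values were seen. On 2L the window from 21.4 to 21.5 Mb held 14 list B peaks without a partner and no such list A peak, while permuted labels gave an excess of at most 3 in any 2L window. The permutations treated peaks as independent, so that limit is no fair reference if the 14 are copies of a repeat. The next window, to 21.6 Mb, held 9 list B and 2 list A peaks without a partner. The list B peaks without a partner in both windows spanned a block of 126 kb, from 21417169 to 21543219, in which list B had 25 peaks and list A had 2. Both list A peaks were shared, and 23 list B peaks were not. These 23 were 39.0% of all list B arm peaks without a partner, of which 36 lay elsewhere. Their summits recurred at a median distance of 5.04 kb, and 19 of the 22 distances lay within 10% of it. On Uextra, the stretch from 28 Mb to the last peak held 57 list A peaks and 249 list B peaks, a ratio of 4.37. The rest of Uextra held 935 and 1063, a ratio of 1.14. Before the end, list B had more peaks than list A in every bin of 1 Mb from 21 to 28 Mb. Examples are the bins from 21 to 22 Mb (20 against 13), 25 to 26 Mb (24 against 10) and 27 to 28 Mb (46 against 25). This was not particular to that stretch, since list B also had more in every bin from 3 to 15 Mb. Examples there are the bins from 3 to 4 Mb (42 against 39) and 14 to 15 Mb (47 against 39).

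**Figure D3:**
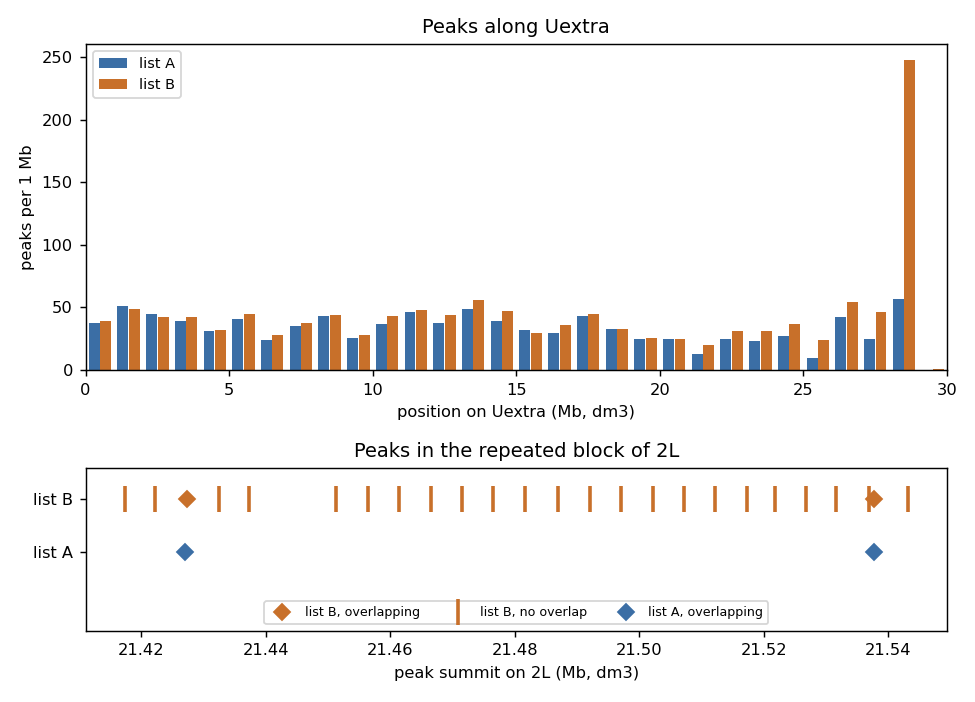
Top, peaks per 1 Mb along Uextra in list A (blue) and list B (orange). In the last full bin list B has 248 peaks and list A has 57, while in no other bin does either list exceed 56. Bottom, peak summits on 2L in the block from 21417169 to 21543219, with diamonds for peaks that overlap the other list and ticks for those that do not. The 23 ticks, all in list B, recur at a median of 5.04 kb.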

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

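The alternatives that left out regions or merged peaks within 500 bp were chosen after seeing the data; the others were planned. Merging within 100 bp joined no peaks, so that setting says nothing. Over the other 10 settings and 21 results, 53 of 121 values stayed within the interval (or within 1.5 times) of the reported one, 68 moved and 0 reversed. Apart from the arm odds ratio and the width ratio, the results were shares, counts, percentiles or an index, which have no sign to reverse. Some could not change, such as the class shares of list B when only list A was trimmed. List A kept the higher arm share, with an odds ratio whose interval was above 1, in each setting that gave one.

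With a reciprocal overlap of 50%, 61.8% of list A and 78.9% of list B were shared, and the median list A peak without a partner stood at percentile 24.1. In the stronger 50% of each list (2572 and 2013 peaks) 68.7% and 89.1% were shared, with a Jaccard index of 0.724. The arms held 67.7% and 52.9%, the unplaced scaffolds 27.6% and 41.6%, and proximal peaks were 8.61% of list A arm peaks and 10.9% of those of list B (odds ratio 0.771, 0.597 to 0.995). The log2 width ratio, -0.088 over all pairs, was -0.046 there, and 13 windows had a list A and 6 a list B excess. On the arms and chromosome 4 alone, 57.6% and 97.4% were shared, the Jaccard index was 0.677 and the width ratio -0.20. With list A trimmed, the shares were 79.5% and 82.1%, the index 0.740, and the arms and unplaced scaffolds held 69.8% and 25.5% of list A. Within 1 Mb of the proximal ends lay 4.71% and 6.32% of arm peaks (odds ratio 0.732, 0.583 to 0.919). Windows of 50 kb gave 47 with a list A excess.

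Merging within 500 bp gave shared values of 68.5% and 86.7%, an index of 0.699, arm shares of 68.7% and 52.8%, Het shares of 3.09% and 3.76%, unplaced shares of 28.02% and 43.2%, and 24 windows with a list A excess. Without Uextra, 61.2% and 97.0% were shared, the arms held 88.5% and 83.3%, the Het scaffolds 5.15% and 7.33%, and U alone 6.02% and 8.99%. The odds ratio was then 1.54 (1.34 to 1.77) for the arms and 0.687 (0.563 to 0.838) for the Het scaffolds, whose interval had included 1 with Uextra. The median list-only peak stood at percentile 22.8 in list A and 9.48 in list B, the width ratio was -0.15, and 2 windows had a list B excess. With list A then also trimmed, to 2715 peaks, 81.8% and 85.6% were shared, the index was 0.756, and the arms, Het scaffolds and U held 87.4%, 5.52% and 6.78% of list A. The odds ratio was 1.39 (1.19 to 1.62) for the arms and 0.739 (0.594 to 0.920) for the Het scaffolds. Without the 2L block and the end of Uextra, 92.8% of list B was shared, the index was 0.725, and the arms and unplaced scaffolds held 59.6% and 34.8% of list B. The odds ratio was 1.76 for the arms and 0.784 (0.644 to 0.956) for the Het scaffolds, the list B percentile 22.7, and 1 window had a list B excess.

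No paired analysis was possible because no label ties a list to a library, pair or group; leaving out replicates was not possible for the same reason. The planned results for promoters and gene lists were not run, as no dm3 annotation was used here. Read depth is unknown, so weak peaks missing from a list are not shown to be closed.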

Other observations

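Of the tests here, those on Uextra, on the 2L block and on the length of list A were chosen only after the result was seen, while that on weak arm peaks was set out before its value was computed. No pattern can be given a biological cause from the design, because the lists carry no condition, and no list was assigned to the knockdown from what it contains.

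The first pattern is that list A peaks on the major arms lacked a list B partner more often than scaffold peaks did. A loss of peaks of low strength alone would give an odds ratio near 1 at equal strength, and the value was 16.2 (12.3 to 21.3). Strength is an area, so a wide, low peak and a narrow, high peak of equal strength can differ in q. A loss of the peaks with the lowest q was not tested and stays open. The same limit holds for the trimming below, which was by strength. The greater length of list A alone would leave an odds ratio near 1 after trimming to 4027 peaks, if arm and scaffold peaks were equally strong. The value was 16.5 (11.3 to 24.3). It was not split by strength, so it does not test length and strength together. With Uextra left out first it was 43.2 (10.7 to 174), with 2 scaffold peaks without a partner. The test planned for this compared arm shares after trimming (odds ratio 1.81, 1.65 to 1.98), which list B peaks on Uextra alone can raise, so it was not used. Open remain a lower share of reads from the arms in the libraries behind list B, a change in how reads of repeats were placed, and an effect of H1, none of which the lists can separate. A hypothesis that also covers the narrower arm peaks of list B is that its arm signal was lower relative to its scaffold signal, which may be technical or biological.

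The second pattern is the crowd of list B peaks at the end of Uextra. Of the 411 list B peaks without a partner on Uextra, 48.4% were in the fullest bin, the last. A gain spread along Uextra like its list A peaks gave a mean of 6.60% in whichever bin was fullest, and at most 10.2% over 10000 draws. The draws treated peaks as independent, so that limit is no fair reference if these peaks are copies of a repeat. Calls near the threshold were tested by strength. Of the 199 list B peaks without a partner there, 66 (33.2%, 26.7 to 40.2) were in the stronger 50% of list B. Strength is an area, so that share cannot show how many of the calls lay near the threshold in q. The strongest of the 199 had a −log10 q of 5.57, against a lowest value of 1.54 in list B, so not all lay near it. The bound of 25% for that test was set after some of these peaks had been seen. Sequence of these scaffolds was not used here, so repeats, DNA of another organism and fly heterochromatin all remain open.

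The third pattern is the row of list B peaks on 2L. Copies of a tandem repeat would recur at a fixed distance, but the regular spacing, with 19 of 22 distances within 10% of the median, is itself what drew attention to the block. It therefore cannot test that explanation, which stays open, and whether the 23 peaks are independent is not known. The arm 2L has 112 histone genes in the Release 6 table, with 23 copies of the H1 gene His1, 22 of them between other histone genes. Whether the block holds these genes was not tested, for want of a dm3 annotation. By strength, 34.8% of the 23 were in the stronger 50% of list B (16.4 to 57.3). That share cannot decide whether they were calls close to the threshold, because the peaks are too few. The −log10 q of the 23 ran from 1.61 to 2.47, against a lowest value of 1.54 in list B. Because the caller's cutoff is not given, q does not decide the question either.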
